A study of Mus musculus with 6 samples.

How the data were processed

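Bulk RNA sequencing of mouse inner ear was analysed in 6 libraries, 3 from wild-type mice (WT) and 3 from mice carrying a Pou3f4 mutation (Pou3f4 KO). Per the labels' protocols, total RNA was extracted with TRIzol, and poly(A)-selected libraries were made with a TruSeq Stranded mRNA kit, which keeps the strand of the transcript. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and HTSeq, without versions, and the mouse build mm10. Which of these tools made the table, which annotation release was used and whether reads were counted by strand are not given in the sources used here. The authors deposited a table of read counts per gene, whole numbers that had not been normalised, with an Ensembl gene identifier, a symbol, a biotype and coordinates for each of 55401 genes. Every gene had a name, and 34032 genes had at least 1 count.

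Of the gene identifiers, 55141 were found in the GENCODE M21 annotation of the same build, 54821 of them with identical coordinates. Exons of that annotation were used to find named genes that overlap another gene. Reads in overlapping exons of the same strand appear to have been counted for both genes, since Igf2 held 214191 counts and the overlapping model Gm49394 held 213593. Genes lying almost wholly inside exons of a gene on the opposite strand had a median read density of 209.9% of the host (36 genes), against 130.4% for those on the same strand (19 genes). Both medians lie above the density of the host and can include reads of the nested genes themselves, so they do not show whether strand was used. Tsix, on the opposite strand over 11.0% of the exons of Xist, held only 0.8% of the counts of Xist. That is few if reads of both strands were counted for both genes, but it is 1 pair, so the use of strand was not settled. Levels of named genes with overlapping exons are uncertain for that reason, and the overlap is given beside them as a share of their exon length.

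Counts were analysed as deposited. Library totals ranged from 18409409 to 23323953 counts, and a count of 0 allowed up to 3 reads, or 0.129 to 0.163 CPM (counts scaled to a library total of 1000000), as a limit of counting error only. Genes were kept with the filterByExpr function of edgeR at its minimum count of 10, which left 19687 genes. Library sizes were scaled by TMM, and CPM values use these scaled sizes. The groups were compared with the quasi-likelihood F test of edgeR (glmQLFit and glmQLFTest, design with the genotype alone), and p-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05 and no minimum fold change. Fold changes are KO over WT on the log2 scale, with the standard error (SE), and levels are means with the standard deviation (SD) over the 3 libraries of a group. The labels do not say whether the libraries came from separate animals. Sex-linked reads, given below, differed between libraries within each genotype, so not all libraries of a genotype came from the same animal. Those with the same sex-linked reads may still have. The p-values thus measure only the spread between these samples, part of which may be technical. Each library was counted as a replicate because the labels number it as one.

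Before the data were examined, 32 gene lists for the cell types and pathways of the ear, its surrounding bone and marrow, and pigment cells were fixed, and 31 of them had at least 3 tested genes. The list of Xist and 4 Y-linked genes had only Xist among the tested genes and was described, not tested. Lists were tested with camera of limma on log2 CPM (prior count 2, preset correlation between genes of 0.01), which compares the genes of a list with all other genes. The same test with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, were run beside it. For these lists, fits without 1 library were tested with the preset correlation alone. For each list, members past the threshold are counted over all genes tested and also adjusted over the list alone.

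The genes named were fixed by a rule. They were Pou3f4, the 12 genes with the largest change in each direction among those past the threshold with a mean of at least 1 CPM and no overlap between the libraries of the groups, up to 4 members past the threshold of each list, and, for lists without any, up to 2 members with the highest mean CPM, given as values. Results of some genes that the rule takes are not reported here. Gene models without a proper name were only counted, and any other gene was chosen after its values were seen, which covers members named because DESeq2, a fit without 1 library or the list alone called them. Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom, the replicate number as a block, leaving out mitochondrial, haemoglobin and muscle genes, leaving out each library, stricter thresholds, and for lists the estimated correlation, fry, and leaving out genes shared between lists. Library quality weights (limma), a term for the presence of Xist reads, robust edgeR and lists without Pou3f4 were added after the data were seen, as were lists of keratinocyte genes and of collagen-processing genes. No batch, litter or day is given in the labels.

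The test was checked on counts simulated from the means and library sizes of these libraries (19687 genes, 5 simulations, 200 genes changed). It recovered 37.4% of genes changed 2-fold and 88.0% of those changed 4-fold, and 6.6% of its calls were false. A further simulation with nothing changed gave 0 calls. Genes were drawn independently, with the same dispersion for a gene in both groups. The real libraries had a coefficient of variation of 31.6% in WT and 10.6% in KO, and genes of a cell type moved together in them. The simulated rates therefore need not hold for these data. The work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.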

Results

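Transcripts of the whole inner ear were measured by bulk RNA sequencing in wild-type mice (WT, n = 3 libraries) and in mice mutant for Pou3f4 (Pou3f4 KO, n = 3 libraries). Pou3f4 is an X-linked POU-domain transcription factor of the mesenchyme around the developing ear, and its loss causes deafness. The comparison of genotypes was made to look for transcripts behind the pigmentation of the mutant ear. The labels describe the material as inner ear cells of every type and give no age, sex or dissection. Total counts were 18542720, 18409409 and 19133386 in WT replicates 1 to 3. They were 23323953, 23146882 and 18883922 in KO replicates 1 to 3.

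Pou3f4 itself (ENSMUSG00000056854, mm10 chromosome X, 110814280 to 110817207, plus strand) fell 58.8-fold in the KO libraries. Its level was 94.5 ± 31.3 CPM in WT and 1.60 ± 0.370 CPM in KO (SD, n = 3 each), a log2 fold change of −5.88 (SE 0.35, adjusted p = 0.0128, edgeR). The WT libraries held 1044, 2140 and 2233 Pou3f4 counts and the KO libraries 45, 28 and 30, so the gene matched the genotype label in every library. The labels do not say which part of the gene the mutant allele lacks. WT replicate 1 had the lowest WT level, 58.3 CPM against 112 and 114 CPM. The adjusted p exceeded 0.05 without WT replicate 3 (0.0808), KO replicate 1 (0.257), KO replicate 2 (0.15) or KO replicate 3 (0.265), with log2 fold changes of −5.72, −6.06, −5.71 and −5.89.

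Sex-linked transcripts did not follow the genotype. Xist, the transcript of the inactive X chromosome, held 11165 and 9143 counts in WT replicates 1 and 2 and 15783 and 15119 counts in KO replicates 2 and 3. It held 6 counts in WT replicate 3 and 1 count in KO replicate 1. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty showed the opposite pattern, with 3160 counts in WT replicate 3, 4545 in KO replicate 1 and 0 in the other 4 libraries. A count of 0 allows up to 0.163 CPM per gene there. The mutant genotype is written as hemizygous (Pou3f4y/-) in the labels, and KO replicates 2 and 3 held Xist and no Y-linked reads. Each genotype thus had 2 libraries with Xist and 1 with Y-linked reads, and the fold change of Xist, whose exons overlap Tsix on the opposite strand over 11.0%, was 0.45 (SE 2.2, adjusted p = 0.932, edgeR). With the presence of Xist as a term in the model, an alternative added after the data were seen, 0 genes passed the threshold and 3185 had an unadjusted p under 0.05.

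**Figure D1:**
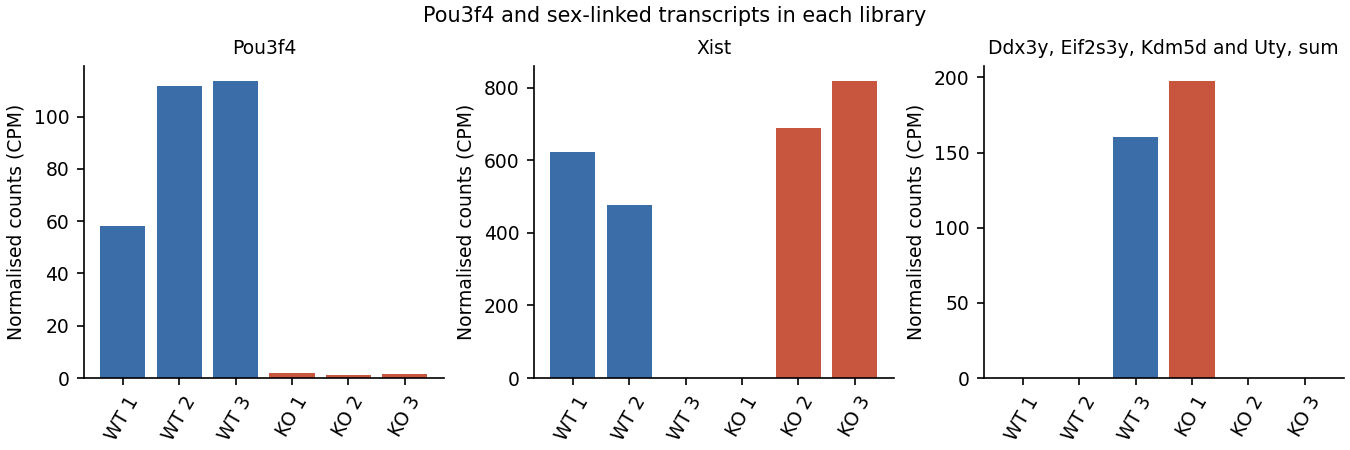
Normalised counts (CPM, vertical axis from 0) of Pou3f4, Xist and the summed Y-linked genes in each of the 6 libraries (bars; blue WT, red Pou3f4 KO). Pou3f4 lies at 58.3 CPM or more in the WT libraries and at 1.96 CPM or less in the KO libraries, while Xist and Y-linked reads split both genotypes.

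Of 19687 genes tested, 78 changed between the genotypes, 42 higher and 36 lower in the KO libraries. The largest rises among the named genes were of Lipi, a phospholipase (1.91, SE 0.22, adjusted p = 0.049), and Aldh1l2, a mitochondrial enzyme of folate metabolism (1.41, SE 0.14, adjusted p = 0.0387). Galnt5, which starts O-linked glycosylation (1.27, SE 0.15), and Tent5a, a poly(A) polymerase needed for collagen expression in bone (1.27, SE 0.10), came next. They were followed by Cgref1 (1.24), the matrix glycoprotein tenascin C, Tnc (1.17), and the collagenase Mmp13 (1.16) and Fam167a (1.11). The chaperone Fkbp11 (1.06), the type I collagen chains Col1a2 (1.04) and Col1a1 (1.01), and the bone morphogenetic protein family member Bmp3 (1.02) completed the rises. After Pou3f4, the largest falls were of Cpm, a membrane carboxypeptidase (−1.96, SE 0.12, adjusted p = 0.0128), and Fa2h, which makes the hydroxylated lipids of myelin (−1.79, SE 0.23). The neuropeptide precursor Vgf (−1.76, SE 0.24), Art3 (−1.52, SE 0.12, adjusted p = 0.0289) and Otor (−1.42, SE 0.15) fell next. The rank of Fa2h rested on WT replicate 1, at 76.0 CPM against 43.0 and 44.3 CPM in WT replicates 2 and 3. Without WT replicate 1 its change was −1.49, smaller in size than those of Vgf (−1.83) and Otor (−1.57). Pmp22 (−1.26), Pou3f1 (−1.19), Parm1 (−1.19), Col28a1 (−1.18) and Car3 (−1.17) were among the other falls, with SE of 0.11 to 0.16. The 78 genes had no overlap between the libraries of the groups, as did 27.7% of all genes tested. Chance gives 10% only where the libraries of both groups are exchangeable. The coefficient of variation was 31.6% in WT against 10.6% in KO, and genes move together, so the share by chance can be higher here. The excess over 10% therefore does not measure an effect of genotype. For 57 of the 78 the adjusted p was the same, 0.049. The number of genes moved to 1814 without WT replicate 1 and to 760 without WT replicate 2, each including all 78. DESeq2 called 1505, also including the 78. It was 0 without WT replicate 3, KO replicate 1, KO replicate 2 or KO replicate 3 (3364, 2199, 2638 and 2087 genes with an unadjusted p under 0.05, edgeR), with the direction of each of the 78 genes kept. Exons of Aldh1l2 overlap D10Wsu102e on the opposite strand over 14.1% of their length, and those of Pou3f1 overlap Gm2164 over 8.6%. Those of Galnt5, Tnc and Art3 overlap a neighbour over 5.3% or less, so part of the reads of Aldh1l2, Galnt5, Tnc and Art3 may be shared. Gm2164 held only 2 counts against 1372 for Pou3f1, so few reads of Pou3f1 are shared if overlapping reads were counted for both genes.

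**Figure D2:**
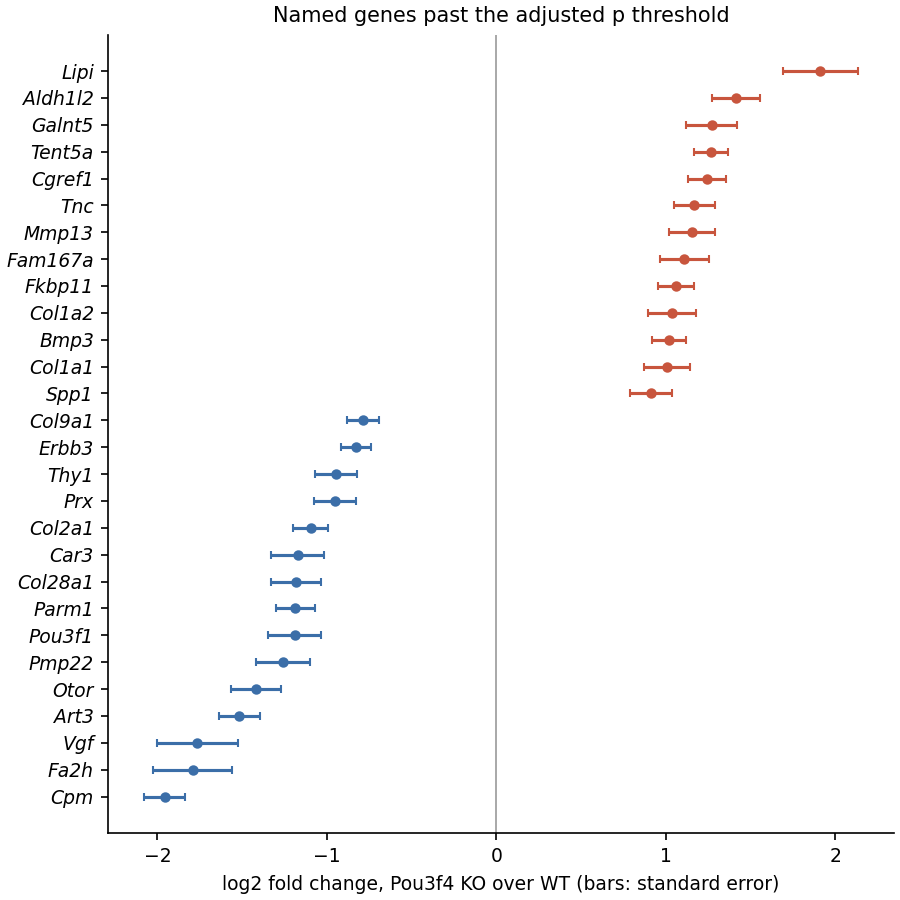
Log2 fold change (KO over WT, horizontal axis) with its standard error (bars) for 28 named genes past the threshold other than Pou3f4, in red where higher and in blue where lower in KO. Values run from −1.96 for Cpm to 1.91 for Lipi.

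Pigment genes were the subject of the comparison. Of the 15 tested genes of melanin synthesis and the melanosome, 0 passed the threshold over all genes with edgeR (3 at an unadjusted p under 0.05) and 0 when adjusted over the list alone, and 12 had fitted changes above 0. Rab38, a GTPase of melanosome transport chosen after its values were seen, stood at 12.6 ± 1.02 CPM in WT and 17.9 ± 0.407 CPM in KO (0.50, SE 0.11, adjusted p = 0.115, edgeR). It was the only list member called higher with DESeq2 (adjusted p = 0.0163) and without WT replicate 1 (adjusted p = 0.0438, edgeR). The melanin enzyme Dct stood at 56.2 ± 17.1 CPM in WT and 71.8 ± 8.06 CPM in KO (0.35, SE 0.23, adjusted p = 0.437). Tyr stood at 8.32 ± 2.30 and 9.87 ± 1.34 CPM, and Tyrp1 at 4.02 ± 2.38 and 4.10 ± 0.351 CPM. The melanosome protein Pmel stood at 10.7 ± 2.86 and 15.7 ± 3.85 CPM and the melanosome motor Myo5a at 128 ± 4.25 and 141 ± 5.99 CPM. Mreg, a melanosome transport gene and the list member with the largest fitted change in size, had a fitted change below 0, at 8.40 ± 3.49 CPM in WT and 4.58 ± 0.203 CPM in KO (−0.87, SE 0.31, adjusted p = 0.196). Tyr, Tyrp1, Pmel and Mreg were singled out after their values were seen. As a list these genes were higher in KO relative to all other genes, with a median log2 fold change of 0.24 (camera adjusted p = 0.0337, and adjusted p = 0.547 with an estimated correlation). The median was 0.10 without WT replicate 1 (adjusted p = 0.181) and 0.14 without KO replicate 3 (adjusted p = 0.0699), and 0.38 without WT replicate 2 (adjusted p = 0.0164). The list mean in WT replicate 1 was 2.76 log2 CPM, against 3.04 to 3.31 in the other 5 libraries.

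Of the 11 tested genes of the melanocyte lineage, only Erbb3, a neuregulin receptor that Schwann cells also use, fell (−0.83, SE 0.09, adjusted p = 0.0474, 1.78-fold, 40.7 ± 2.94 against 22.9 ± 0.200 CPM). It was also the only gene past the threshold when adjusted over the list alone and the only one that DESeq2 called, while Snai2 (higher) and Sox10 (lower) passed beside it without WT replicate 1. Mitf, the regulator of melanocyte identity, stood at 18.8 ± 3.91 CPM in WT and 20.1 ± 1.39 CPM in KO, and Kit at 29.7 ± 5.31 and 31.4 ± 1.59 CPM, both chosen after their values were seen. The list did not pass (median −0.15, camera adjusted p = 0.497). Stria vascularis genes did not pass as lists either. The marginal cell and ion transport list had a median of −0.07 (14 genes, adjusted p = 0.497). The intermediate and basal cell list had a median of −0.03 with the test pointing higher (9 genes, adjusted p = 0.497). Of the marginal cell genes, Slc12a2 stood at 225 ± 31.1 CPM in WT and 198 ± 11.3 CPM in KO. Of the intermediate and basal cell genes, Nrp2 stood at 381 ± 6.98 and 583 ± 59.5 CPM (adjusted p = 0.0614, past the threshold when adjusted over the list alone), and Atp1b1, whose exons overlap Nme7 over 18.7%, at 460 ± 144 and 316 ± 39.2 CPM. Counts past the threshold when adjusted over the list alone were 1 in each strial list. Over all genes 0 passed with edgeR (2 and 3 at an unadjusted p under 0.05), while DESeq2 called Wnk2 lower in the marginal cell list and Nrp2 higher (adjusted p = 4.95e-06) in the other. The marginal cell list was lower in KO without WT replicate 1 (median −0.35, adjusted p = 0.0107), where edgeR called 2 of its genes lower, and 1 gene higher and 3 lower in the other list.

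Genes of Schwann cells and myelin were lower in KO as a group. All 11 tested members had negative fold changes, with a median of −0.97 (camera adjusted p = 5.43e-08, and adjusted p = 0.547 with an estimated correlation). Over all genes tested 3 fell, and 9 when adjusted over the list alone. Pmp22, a protein of peripheral myelin (ENSMUSG00000018217, chromosome 11, 63128982 to 63159547), fell 2.39-fold, from 1127 ± 225 to 471 ± 41.8 CPM (−1.26, SE 0.16, adjusted p = 0.049), and periaxin, Prx (ENSMUSG00000053198, chromosome 7, 27497388 to 27520214), fell 1.94-fold, from 227 ± 34.0 to 117 ± 5.93 CPM. Exons of Prx overlap Gm15541 on the opposite strand over 5.4%. Spiral ganglion neuron genes were lower too, with 14 of 14 fold changes below 0 and a median of −0.64 (camera adjusted p = 0.000105, and adjusted p = 0.547 with an estimated correlation). The surface glycoprotein Thy1 fell 1.93-fold, from 74.2 ± 7.65 to 38.5 ± 4.96 CPM (−0.95, SE 0.12, adjusted p = 0.049), the only neuron gene past the threshold over all genes with edgeR. In that list 6 passed when adjusted over the list alone and 6 with DESeq2, which called 9 Schwann cell genes. At the preset correlation of 0.01 the camera calls of both lists held without each library in turn (largest adjusted p 5.46e-06 and 0.0104), and the neuron median was −0.41 without WT replicate 2. The estimated correlations were 0.78 for Schwann cell and 0.48 for neuron genes, so these p-values understate the spread between libraries. Skeletal muscle genes made up 0.641%, 0.016% and 1.15% of counts in WT replicates 1 to 3 and 0.003%, 0.087% and 0.004% in KO replicates 1 to 3. The Schwann cell mean did not follow them within WT, at 7.26, 8.12 and 7.93 log2 CPM, and lay at 6.79 to 6.89 log2 CPM in KO.

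Sensory epithelium lists did not pass. Hair cell genes had a median of −0.07 (16 genes, camera adjusted p = 0.939, the test pointing higher) and supporting cell and tectorial membrane genes a median of −0.09 (13 genes, adjusted p = 0.987). Both had 0 members past the threshold over all genes with edgeR (2 and 4 at an unadjusted p under 0.05; DESeq2 called 0 and 1, Prox1, which was lower) and 0 when adjusted over the list alone. Myo7a stood at 19.5 ± 5.17 CPM in WT and 22.5 ± 3.13 CPM in KO, and Otof at 13.7 ± 7.12 and 13.4 ± 2.29 CPM. Tectb, overlapped over 1.5% of its exons, stood at 77.4 ± 6.05 and 94.9 ± 6.14 CPM and Fgfr3, overlapped over 13.9%, at 78.6 ± 22.7 and 74.6 ± 1.46 CPM. The mean of the hair cell list was 1.12 log2 CPM in WT replicate 1 and 1.87 to 2.37 log2 CPM in the other libraries. Without WT replicate 1 the hair cell list was lower in KO, with a median of −0.35 and an adjusted p of 0.0262.

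In the otic mesenchyme and spiral ligament, the tissue in which Pou3f4 is active, 14 of 16 tested genes had fold changes below 0, with a median of −0.50 (camera adjusted p = 0.00171, and adjusted p = 0.351 with an estimated correlation). Otor, a secreted protein of the cochlea (ENSMUSG00000027416, chromosome 2, 143078473 to 143081713), fell 2.67-fold, from 349 ± 63.2 to 131 ± 6.39 CPM. The carbonic anhydrase Car3 (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523) fell 2.25-fold, from 957 ± 191 to 425 ± 15.6 CPM. These were the 2 members past the threshold over all genes, and 3 passed when adjusted over the list alone, the other being Emilin2. The list kept its call without each library in turn (largest adjusted p 0.00513) and also passed with fry (adjusted p = 0.00682). Among the POU3 family, Pou3f1, a regulator of Schwann cell myelination, fell 2.28-fold beside Pou3f4, from 16.1 ± 1.60 to 7.05 ± 0.928 CPM. Pou3f3 stood at 55.5 ± 11.6 and 64.5 ± 3.24 CPM and Pou3f2 at 6.60 ± 2.59 and 5.67 ± 0.736 CPM. The list of these 4 genes contains Pou3f4, whose change the genotype itself fixes, and without it the list did not pass (3 genes, median −0.22, camera adjusted p = 0.299). With Pou3f4 the median was −0.70 (camera adjusted p = 0.0144, adjusted p = 0.547 with an estimated correlation, and adjusted p = 0.103 without WT replicate 2). Of the 4 genes 2 were lower over all genes and 2 when adjusted over the list alone.

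Cartilage genes were lower in KO as a list, with 10 of 11 fold changes below 0 and a median of −0.79 (camera adjusted p = 0.00168, and adjusted p = 0.547 with an estimated correlation). Over all genes 2 of the 11 fell, and 3 when adjusted over the list alone. Type II collagen, Col2a1 (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695), fell 2.14-fold, from 6020 ± 368 to 2819 ± 262 CPM (−1.09, SE 0.10, adjusted p = 0.0387). Col9a1 (ENSMUSG00000026147, chromosome 1, 24177610 to 24252684) fell 1.72-fold, from 1101 ± 72.0 to 639 ± 36.1 CPM (−0.79, SE 0.09, adjusted p = 0.049). WT replicate 2, the WT library with the least muscle, had a cartilage mean of 7.04 log2 CPM, against 8.09 and 7.93 in WT replicates 1 and 3 and 6.88 to 7.26 in the KO libraries.

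Type I collagen and tenascin C rose. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) rose 2.01-fold, from 15598 ± 2430 to 31361 ± 2357 CPM. Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) rose 2.05-fold, from 17593 ± 3022 to 36127 ± 1821 CPM. Tnc (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015) rose 2.25-fold, from 823 ± 106 to 1848 ± 130 CPM. These were the 3 of 22 extracellular matrix genes past the threshold over all genes, and 5 rose when adjusted over the list alone. The whole list did not pass: its median of −0.17 and mean of −0.16 lay below 0 while the test pointed higher (camera adjusted p = 0.194). Without WT replicate 1 its median was 0.29 and it was higher in KO (adjusted p = 0.000232). Among 12 osteoblast and osteocyte genes, osteopontin, Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose 1.88-fold, from 4397 ± 643 to 8271 ± 399 CPM (0.91, SE 0.12, adjusted p = 0.049). It was the only member past the threshold over all genes with edgeR (DESeq2 called 3), and 3 rose when adjusted over the list alone. That list had a median of 0.51 (camera adjusted p = 0.00305, adjusted p = 0.547 with an estimated correlation, and adjusted p = 0.092 without WT replicate 1). Exons of Spp1 overlap the gene model Gm42793 on the same strand over 18.8% of their length.

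Genes of bone-resorbing osteoclasts were higher in KO, with 9 of 9 fold changes above 0 and a median of 0.88 (camera adjusted p = 2.28e-06, and adjusted p = 0.547 with an estimated correlation). With edgeR 0 of the 9 passed the threshold over all genes (8 at an unadjusted p under 0.05), while DESeq2 called 7, among them Ctsk (adjusted p = 0.00016) and Mmp9 (adjusted p = 0.000963), and 8 passed when adjusted over the list alone. The collagen-degrading protease Ctsk stood at 2164 ± 564 CPM in WT and 4139 ± 175 CPM in KO, and the gelatinase Mmp9 at 2111 ± 367 and 3371 ± 175 CPM. At the preset correlation of 0.01 the list kept its camera call without each library in turn (largest adjusted p 8.65e-06), with a median of 0.56 without WT replicate 1. The estimated correlation was 0.78, so these p-values understate the spread between libraries. Macrophage genes, 15 of 19 with fold changes above 0, had a median of 0.48 (camera adjusted p = 0.000604, and adjusted p = 0.351 with an estimated correlation), and of 0.28 without WT replicate 1 (adjusted p = 0.000232). Lysosome genes, 12 of 14 above 0, had a median of 0.22 (camera adjusted p = 0.00168, and adjusted p = 0.547 with an estimated correlation). In these lists 0 genes passed over all genes with edgeR (9 and 7 at an unadjusted p under 0.05), and 6 and 7 when adjusted over the list alone. DESeq2 called 5 macrophage genes higher, among them Csf1r (adjusted p = 5.03e-05), and 1 lower, and 7 lysosome genes higher. edgeR called 8 osteoclast, 3 macrophage and 4 lysosome genes higher without WT replicate 1, and 3, 1 and 3 without WT replicate 2. The receptor Csf1r, which macrophages and osteoclasts share and whose exons overlap Hmgxb3 over 15.1%, stood at 225 ± 35.6 CPM in WT and 376 ± 8.82 CPM in KO, and Lyz2 at 254 ± 104 and 372 ± 19.5 CPM. Psap stood at 1164 ± 74.2 and 1207 ± 36.4 CPM and Ctsb, whose exons overlap Fdft1 over 12.8%, at 775 ± 62.9 and 873 ± 23.8 CPM. WT replicate 1 had the lowest osteoclast mean, 6.38 log2 CPM against 7.15 and 6.92 in WT replicates 2 and 3 and 7.64 to 7.71 in the KO libraries.

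**Figure D3:**
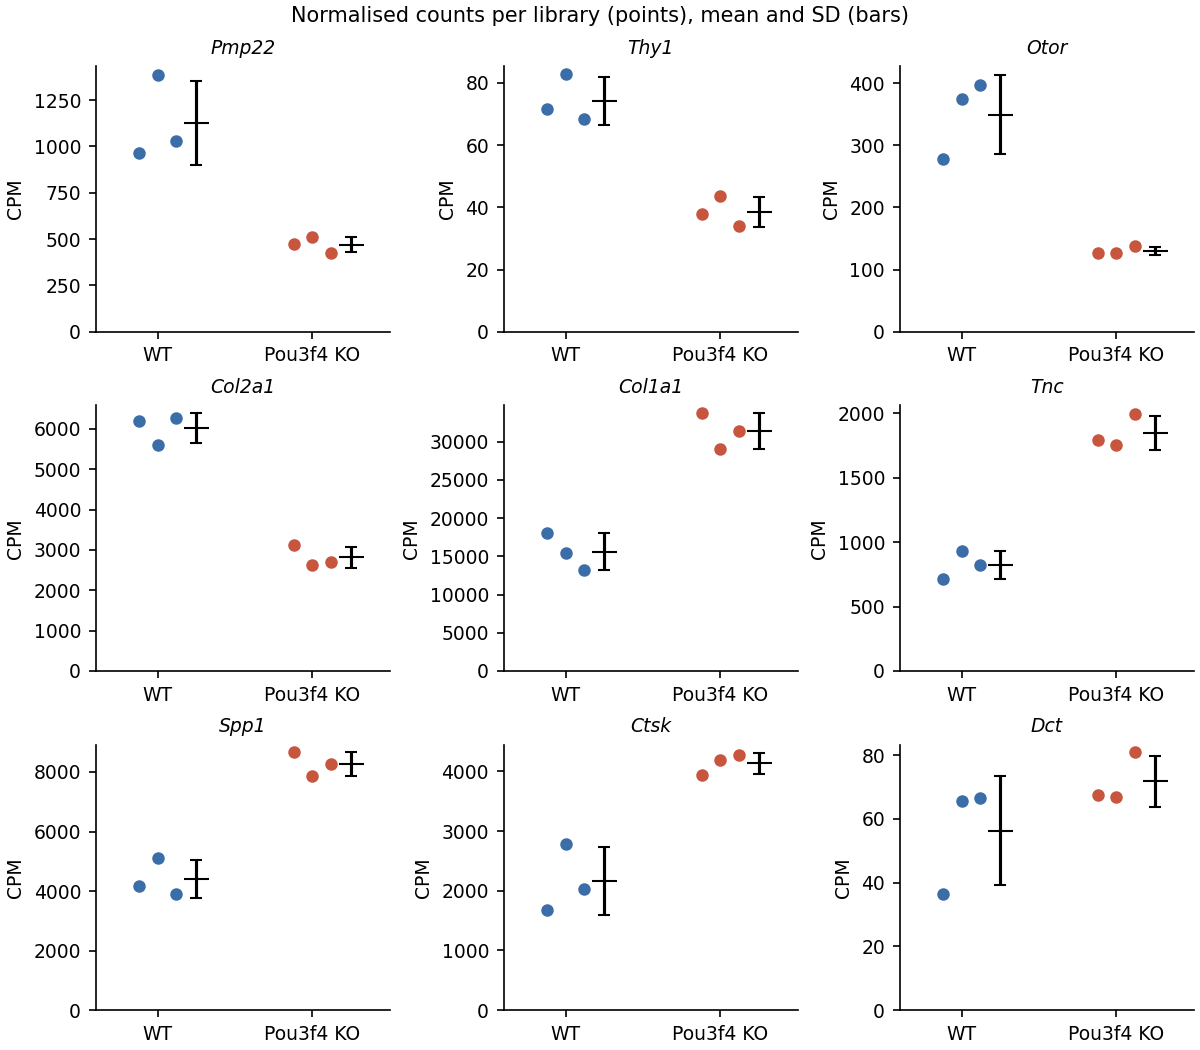
Normalised counts (CPM, vertical axes from 0) of 9 genes in each library (points; blue WT, red Pou3f4 KO) with the mean and SD of the 3 libraries of each group (black). Pmp22, Thy1, Otor and Col2a1 lie lower and Col1a1, Tnc and Spp1 higher in every KO library, Ctsk did not pass over all genes (adjusted p = 0.0887), and the WT and KO ranges of Dct almost meet.

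Of the other immune lists, antigen presentation (median 0.22, camera adjusted p = 0.0141), cytokine, chemokine and NF-kB (median 0.17, adjusted p = 0.0144) and T and NK cell genes (median 0.40, adjusted p = 0.02) were higher in KO. With an estimated correlation the same lists had adjusted p = 0.644, 0.513 and 0.547, and 0 of their members passed over all genes with edgeR (2, 8 and 1 at an unadjusted p under 0.05) or when adjusted over the list alone. DESeq2 called 0, 2 (Il1b and Tlr4) and 1 (Klrb1c), and without WT replicate 1 edgeR called 0, 1 (Il1b) and 1 (Klrb1c). B2m stood at 308 ± 42.6 CPM in WT and 363 ± 17.0 CPM in KO, and H2-D1 at 153 ± 16.9 and 186 ± 12.5 CPM. Cxcl12 stood at 568 ± 155 and 864 ± 61.1 CPM and Vcam1, overlapped over 0.7% of its exons, at 83.2 ± 10.8 and 93.7 ± 6.40 CPM. Cd4 stood at 6.12 ± 1.48 and 8.54 ± 0.908 CPM and Il7r at 2.68 ± 3.16 and 3.27 ± 0.329 CPM. Without WT replicate 3 the adjusted p was 0.215 for antigen presentation and 0.0651 for cytokines, and without WT replicate 1 it was 0.106 for T and NK cell genes. Without WT replicate 2 the medians were 0.34, 0.33 and 1.06, and the cytokine median was 0.29 without WT replicate 1 and 0.11 without WT replicate 3. Complement (median 0.03, adjusted p = 0.471) and interferon response genes (median −0.11, adjusted p = 0.696, the test pointing higher) did not pass, with 2 and 0 members past the threshold when adjusted over the list alone and the same counts over all genes with DESeq2. The complement regulator Serping1 stood at 100.4 ± 30.6 CPM in WT and 90.3 ± 3.71 CPM in KO, and Stat2 at 17.2 ± 3.14 and 15.6 ± 1.13 CPM. Without WT replicate 1 the interferon list was higher in KO (median 0.21, adjusted p = 0.00748).

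Marrow and blood lists did not pass but separated the WT libraries. B lineage genes (median 0.23, camera adjusted p = 0.151) averaged 2.24, 4.78 and 3.10 log2 CPM in WT replicates 1 to 3 and 3.90 to 4.15 in KO. Neutrophil genes (median 0.13, adjusted p = 0.179) averaged 3.05, 5.48 and 5.88 against 5.25 to 5.40, and erythroid genes (median −0.64, adjusted p = 0.391) averaged 5.20, 7.94 and 7.81 against 6.46 to 7.09. S100a9 stood at 234 ± 162 CPM in WT and 311 ± 13.9 CPM in KO, and Ngp at 158 ± 117 and 150 ± 8.05 CPM. Ighm stood at 79.1 ± 56.4 and 96.5 ± 10.9 CPM and Ebf1 at 86.5 ± 6.80 and 73.9 ± 3.55 CPM. Hbb-bs stood at 2223 ± 1169 and 969 ± 242 CPM and Hba-a1 at 1839 ± 969 and 881 ± 209 CPM. With edgeR 0 members of these lists passed over all genes (1, 0 and 2 at an unadjusted p under 0.05) or when adjusted over the list alone, while DESeq2 called Hbb-bs lower (adjusted p = 0.0366). Without WT replicate 1, erythroid (adjusted p = 2.98e-06) and neutrophil genes (adjusted p = 0.0262) were lower in KO, with 7 and 3 members called. Without WT replicate 2, B lineage genes were higher (adjusted p = 1.11e-06), with 4 members called. Without WT replicate 3, neutrophil genes were higher (adjusted p = 0.00513).

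Skeletal muscle genes were lower in KO as a list, with 13 of 13 fold changes below 0 and a median of −4.21 (camera adjusted p = 0.000222, and adjusted p = 0.547 with an estimated correlation), but 0 passed over all genes with edgeR (5 at an unadjusted p under 0.05) or DESeq2, or when adjusted over the list alone. The median was −7.57 without KO replicate 2, and without WT replicate 2 edgeR called 1 member, Actn3. Acta1 ranged from 37.3 to 3850 CPM within WT and from 5.95 to 284 CPM within KO, and Myh1, whose exons overlap Myhas over 8.1%, from 26.3 to 1202 CPM and from 1.83 to 79.1 CPM. Pericyte and smooth muscle genes were lower (10 of 12 below 0, median −0.45, camera adjusted p = 0.00505, adjusted p = 0.547 with an estimated correlation, and adjusted p = 0.0687 without WT replicate 1). Over all genes 0 passed with edgeR (7 at an unadjusted p under 0.05), and 6 when adjusted over the list alone. DESeq2 called 6 lower, among them Rgs5 (adjusted p = 0.00194), and edgeR called 5 without WT replicate 1 and 3 without WT replicate 2. Rgs5 stood at 261 ± 18.6 and 186 ± 16.7 CPM and Pdgfrb at 182 ± 29.4 and 196 ± 14.3 CPM. The pericyte mean was 6.77 and 6.15 log2 CPM in WT replicates 1 and 3, which held the most muscle, 5.51 in WT replicate 2 and 5.27 to 5.47 in KO. Oxidative phosphorylation genes were lower (17 of 18 below 0, median −0.24, camera adjusted p = 0.00061, and adjusted p = 0.547 with an estimated correlation). Atp5b stood at 1236 ± 225 and 938 ± 31.5 CPM and Cox4i1, whose exons overlap Emc8 over 9.9%, at 353 ± 56.5 and 282 ± 8.66 CPM. The oxidative phosphorylation mean was likewise 7.14 and 6.97 log2 CPM in WT replicates 1 and 3, 6.84 in WT replicate 2 and 6.72 to 6.80 in KO. Mitochondrially encoded genes made up 3.85%, 2.96% and 3.91% of counts in WT replicates 1 to 3 and 2.70% to 3.27% in KO.

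Cell cycle genes were higher (14 of 14 above 0, median 0.30, camera adjusted p = 0.00844, adjusted p = 0.692 with an estimated correlation, and adjusted p = 0.351 without WT replicate 1, where the median was 0.06, against 0.46 without WT replicate 2). Mki67 stood at 209 ± 91.9 and 231 ± 54.9 CPM and Top2a, overlapped over 1.4% of its exons, at 133 ± 41.6 and 196 ± 23.4 CPM. In the cell cycle and oxidative phosphorylation lists 0 genes passed over all genes with edgeR (1 and 7 at an unadjusted p under 0.05) or when adjusted over the list alone. DESeq2 called 0 and 1, Ndufa4, which was lower, and without WT replicate 2 edgeR called 0 and 1, Atp5b. Endothelium (median −0.06, adjusted p = 0.262), immediate early and stress (median −0.39, adjusted p = 0.112) and oxidative stress and glutathione genes (median −0.23, adjusted p = 0.233) did not pass, with 1, 0 and 0 members past the threshold when adjusted over the list alone. Over all genes 0 members passed with edgeR (2, 2 and 5 at an unadjusted p under 0.05), while DESeq2 called 1 (Vwf, lower), 0 and 2 (Sod2, lower, and Gpx3, higher). With WT replicate 1 left out, edgeR called Vwf lower, Cdh5 higher, Gpx3 higher and 5 oxidative stress genes lower (Cat, Gclc, Gclm, Sod2 and Gpx1). With WT replicate 2 left out it called Vwf lower and Slc7a11 higher. Cdh5 stood at 123 ± 24.6 and 145 ± 8.51 CPM, and Pecam1 at 116 ± 52.7 and 96.7 ± 5.75 CPM. Egr1 stood at 163 ± 55.0 and 149 ± 44.6 CPM, and Jun, whose exons overlap Junos over 7.3%, at 91.1 ± 78.5 and 39.8 ± 3.90 CPM. Prdx1 stood at 291 ± 25.5 and 315 ± 4.27 CPM and Gpx1 at 298 ± 127 and 248 ± 13.5 CPM. Without WT replicate 2 or KO replicate 2, the immediate early and stress list was lower in KO (adjusted p = 0.0153 and 0.0184).

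**Figure D4:**
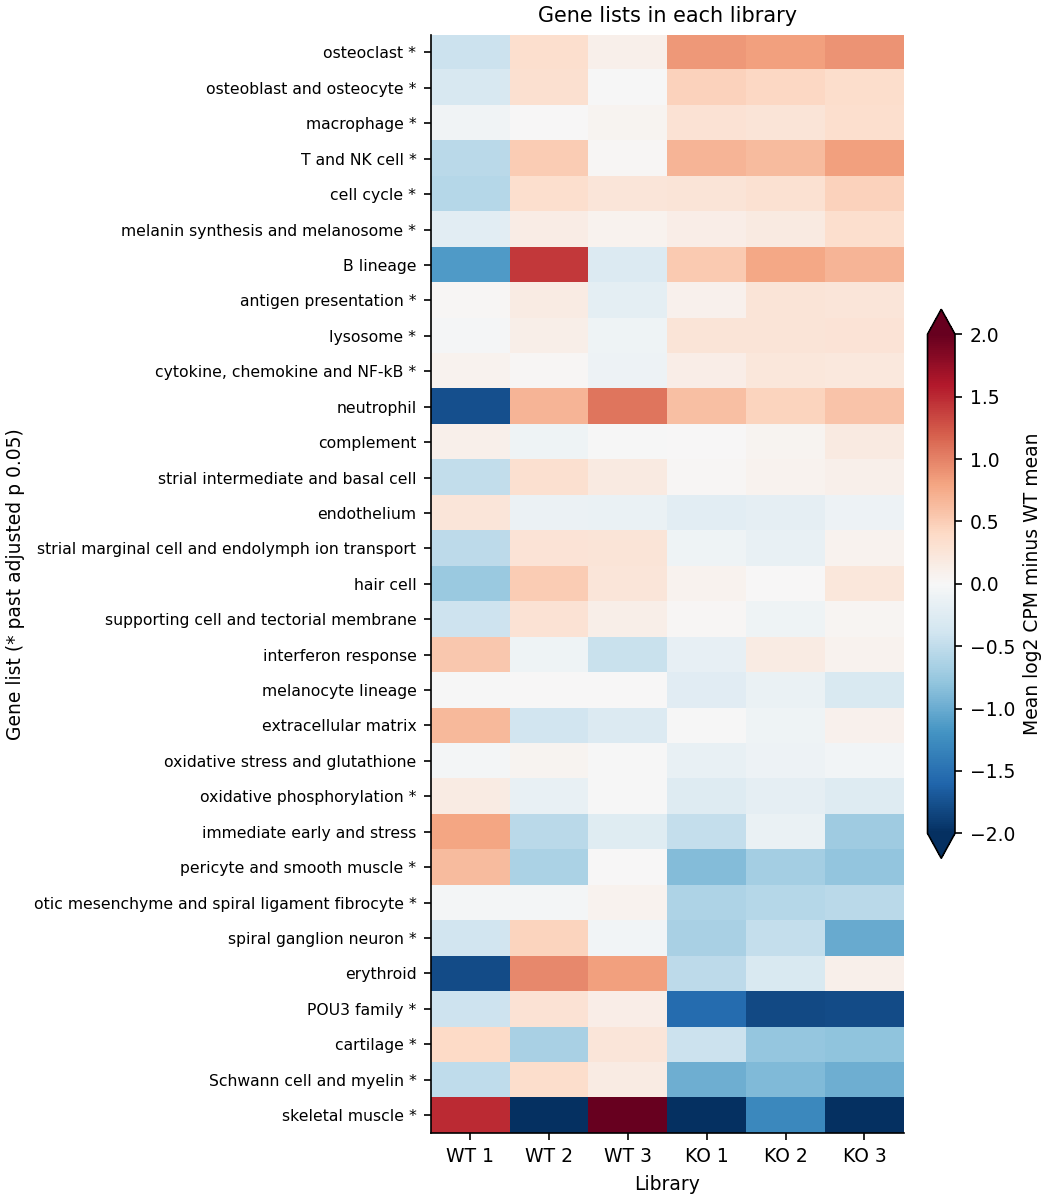
Mean log2 CPM of each tested gene list (rows) in each library (columns) minus the mean of the WT libraries, with colours from −2 to 2 and values beyond at the end colours; asterisks mark the 17 of 31 lists past an adjusted p of 0.05 (camera). Schwann cell, mesenchyme and neuron lists lie lower and osteoclast, macrophage and lysosome lists higher in the KO libraries, while muscle, marrow and blood lists differ most among the WT libraries.

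The WT libraries differed more among themselves than the KO libraries. The biological coefficient of variation was 31.6% in WT and 10.6% in KO, and 24.9% in WT without replicate 1. Spearman correlations across genes, which are not independent replicates, were 0.944 to 0.973 between WT libraries and 0.990 to 0.993 between KO libraries. Not all WT libraries grouped by genotype in this measure. WT replicate 2 correlated with KO replicates 1 to 3 at 0.984, 0.986 and 0.979, above its 0.944 and 0.973 with WT replicates 1 and 3. WT replicate 1 correlated most with WT replicate 3, at 0.962, against 0.941 to 0.954 with the KO libraries. For WT replicate 3 the correlations with the KO libraries were 0.959 to 0.975, against 0.962 and 0.973 with WT replicates 1 and 2. The leading principal component held 55.2% of the variance and placed WT replicate 1 at −84.7, WT replicates 2 and 3 at 20.2 and −34.8, and the KO libraries between 17.3 and 41.6. Over all lists, 17 of 31 passed with camera (9 higher and 8 lower in KO), and 16 with Pou3f4 left out of its list. It was 0 with an estimated correlation (smallest adjusted p 0.351, with 3 lists at an unadjusted p under 0.05) and 3 with fry, which were otic mesenchyme, macrophage (adjusted p = 0.0274) and the POU3 family (adjusted p = 0.0291). With Pou3f4 left out, fry passed 2 lists, and the POU3 family had adjusted p = 0.148. The form of fry that counts changes in either direction passed 18 of 31 lists, the melanin list among them (adjusted p = 0.0286). That form needs no shared direction and does not compare a list with other genes.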

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

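The library quality weights, the Xist term, robust edgeR and the lists without Pou3f4 were tried only after the data were seen, and all other alternatives here were planned. Of the 78 genes, 69 passed with RLE scaling, 71 with upper-quartile scaling (76 called), 72 without a filter (106 called), 78 with the CPM filter (86 called), 71 with limma-voom (80 called), 73 without mitochondrial, haemoglobin and muscle genes (74 called) and 77 with robust edgeR (87 called). DESeq2 called 1505 genes (579 higher and 926 lower, 38.5% higher against 53.8%) and quality weights 1434 (653 and 781), both including the 78, with weights of 0.17 for WT replicate 1 and 0.64 to 3.10 for the others. Requiring a log2 change of 1 left 29 genes (14 higher, 15 lower), testing against a 1.5-fold change left 2 (0 higher, 2 lower), and an adjusted p under 0.01 left 0. The Xist term left 0 (0 and 0). The replicate numbers did not pair the libraries, since deviations of libraries with the same number correlated at −0.13, −0.29 and −0.19. With the replicate number as a block 1 gene passed (0 higher, 1 lower, 0 of the 78), Pou3f4 changed by −5.82 (adjusted p = 0.206), and the 17 lists kept their calls. Leaving out each library gave 0 to 1814 genes (0 to 721 higher, 0 to 1093 lower). All 78 kept their direction in each of these fits, as did the 29 genes past the threshold that the naming rule takes besides Pou3f4. Pou3f4 itself changed by −6.14 to −5.71 without each library (adjusted p = 0.0001 to 0.265) and by −5.89 with the Xist term (adjusted p = 0.0655). Fits without 1 library, all of 5 libraries, called from 0 to 1814 genes, so the number of libraries alone does not account for these differences, and the cause was not tested for any alternative. At these depths a count of 0 leaves open levels up to 0.163 CPM, and the effect of depth on the calls was not tested.

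Of 17 lists past the threshold, 17 held with RLE scaling, the CPM filter, the Xist term and without shared genes, 16 with Pou3f4 left out of the lists, 14 with quality weights, 12 without WT replicate 1, 3 with fry and 0 with an estimated correlation, and all 17 kept their direction. Quality weights added strial marginal cells (lower, adjusted p = 0.0461), extracellular matrix (higher, adjusted p = 0.0107) and erythroid genes (lower, adjusted p = 0.00176), the replicate block added B lineage genes (higher, adjusted p = 0.0431), and lists added without 1 library are given above. The melanin list had a median of 0.24 both with an estimated correlation (adjusted p = 0.547) and with fry (adjusted p = 0.159), 0.19 with quality weights (adjusted p = 0.163), and 0.10 to 0.38 without each library (adjusted p = 0.0164 to 0.181).

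Every gene or list that changed direction was past no threshold in the main fit of all libraries (edgeR for genes, camera for lists), and the cause was not tested. Of these, the strial marginal cell and erythroid lists did pass with quality weights, as given above. With quality weights the log2 change was 0.091 for Fgfr3, 0.056 for Pecam1, 0.032 for Serping1, −0.19 for Mki67 and 0.17 for Egr1. With limma-voom it was 0.087 for Otof, 0.29 for Ngp and −0.58 for Xist, with the replicate block 0.10 for Otof and 0.26 for Ngp, and with the Xist term 0.096 for Ngp. Without each library it ranged from −0.40 to 0.35 for Otof, −0.24 to 0.16 for Fgfr3, −0.45 to 0.17 for Pecam1, −0.29 to 0.11 for Serping1, −0.083 to 1.03 for Ighm, −0.086 to 0.80 for S100a9, −0.56 to 0.57 for Ngp, −0.20 to 1.91 for Il7r, −0.20 to 0.38 for Mki67, −0.36 to 0.17 for Egr1, −0.012 to 0.083 for Psap and −0.13 to 1.07 for Xist.

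For lists whose test changed direction, the median was −0.13 for strial intermediate cells, −0.15 for hair cells and −0.06 for neutrophils with quality weights, −0.07 for hair cells with the CPM filter, and for supporting cells −0.10 with RLE scaling and −0.09 with fry. Without each library medians ranged from −0.35 to 0.09 for strial marginal cells, −0.28 to 0.24 for strial intermediate cells, −0.35 to 0.36 for hair cells, −0.26 to 0.17 for supporting cells, −0.12 to 0.01 for endothelium, −0.31 to 0.21 for the interferon response, −0.43 to 0.57 for neutrophils and −1.19 to −0.23 for erythroid genes.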

Other observations

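The count of other splits, the depth comparison, both tests of the nerve lists and the 3 tests of the sex-linked reads were chosen after their results were seen, and the keratinocyte and collagen-processing lists were written before their tests but after some of their genes had been seen. Genes outside the naming rule, chosen here after their values were seen, included several with known roles in the ear or in secretion. Eya4, a transcriptional cofactor whose loss causes deafness, fell in KO from 86.8 to 45.1 CPM (log2 fold change −0.95, adjusted p = 0.049, lower in 3 of 3 libraries). Reln, an extracellular guidance protein, fell from 37.0 to 17.7 CPM (−1.07, adjusted p = 0.049), and Col9a3, a partner of the type II collagen fibril, fell from 446 to 275 CPM (−0.70, adjusted p = 0.049). The secretory genes Sec24d (0.59), Lman1 (0.60) and Fkbp14 (0.62), the collagen prolyl hydroxylase P4ha1 (0.66), the proline-synthesis enzyme Pycr1 (0.82) and the protease inhibitor Serpine2 (0.87) rose, each with an adjusted p of 0.049 (edgeR). These calls, like the 78 as a whole, held without WT replicates 1 or 2 and were lost without WT replicate 3 or any KO library.

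The 78 genes came from the split of the libraries by genotype, and the other splits into 3 and 3 called at most 0 genes. As 6 libraries make only 10 such splits, of which 1 gave as many genes, they are too few for a share under 0.05. The other splits also mix both genotypes in each group, so any effect of genotype widens their spread and lowers their calls. No conclusion is drawn from them.

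WT replicate 1 stood apart from the other 5 libraries, with Krt5 at 183 CPM against at most 2.34 CPM, and no biological explanation was tested, since the design gives none. Skin taken along with that ear is a candidate source: of 14 further keratinocyte genes, 13 were at least 10 times higher there than in any other library, among them Krt1 (230 CPM against at most 0.76), Krt10 (181 against at most 4.09), Krt14 (168 against at most 1.53) and the cornified envelope gene Lor (19.4 against at most 1.42). Sfn was the exception, at 35.3 against at most 3.86 CPM, and 10 of the 15 genes had at least 1 CPM in another library, so a low level of several belongs to the other libraries too. A lower depth is argued against by the total of WT replicate 1, which was 133311 counts above the lowest of the other libraries. Whether its low marrow and blood genes have the same source stayed open.

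The lower Schwann cell and neuron genes of the KO libraries, seen beside higher bone genes, could come from a larger share of bone diluting every soft tissue. That explanation needs sensory epithelium and strial genes to be lower by as much, but the nerve lists minus those lists differed by −0.85 log2 CPM between KO and WT (2.00 ± 0.235 against 2.86 ± 0.131, SD, n = 3 each), beyond the largest range within a group, 0.465 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The epithelial and strial mean was lowest in WT replicate 1, at 3.61 log2 CPM, against 4.51 and 4.36 in WT replicates 2 and 3 and 4.12 to 4.27 in KO. Without WT replicate 1 those lists had medians of −0.35 to −0.26, against −0.93 for neuron and −1.24 for Schwann cell genes. The values argue only against an equal fall, and dilution as a part of the difference stays open. Against nerve carried in with muscle, WT replicate 2, with the least muscle of the WT libraries, exceeded KO replicate 2 by 1.23 log2 CPM in the Schwann cell list, though it held less muscle (0.016% against 0.087% of counts), and WT replicate 1, with more muscle, had a lower Schwann cell mean (7.26 against 8.12 log2 CPM). These are single libraries, so muscle as a part of the difference cannot be told apart from an effect of genotype. A loss of nerve fibres, Schwann cells or their transcripts with the genotype remains untested.

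KO replicates 2 and 3 held Xist and no Y-linked reads, although the labels write the mutant genotype as hemizygous. A swap with WT libraries is argued against by Pou3f4, which reached at most 1.62 CPM in these 2 libraries against 58.3 CPM or more in WT. Tissue pooled from male and female animals is argued against by the most reads of the 4 Y-linked genes in either library, 0, against 4545 in KO replicate 1. Female animals with no intact Pou3f4 copy could give these values, since Pou3f4 reached at most 1.72% of the WT mean there. That remains a hypothesis, found and tested on the same values, and no effect of sex on the other genes was separated from that of genotype beyond the Xist term.

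The rise of Col1a1 and Col1a2 led to the hypothesis that genes for processing and exporting collagen rose with them. Of 23 such genes, 4 had been seen beforehand (P4ha1, Sec24d, Sec23a and Serpinh1) and were left out. The remaining 19 had a median log2 fold change of 0.29, 14 of them above 0, and were higher relative to other genes (camera p = 0.000515), but p = 0.205 with an estimated correlation, and 0 passed by themselves. Without WT replicate 1 the median was 0.41, with 12 genes higher, 1 lower and p = 0.0496 with an estimated correlation, among them P4ha2 (0.91), Pcolce (0.66) and Bmp1 (0.57), while Plod2 was lower (−0.36). A shared rise of the type I collagen genes and of genes for collagen processing is consistent with these values, while Col2a1, Col9a1, Col9a3 and Col28a1 were lower in KO, and more osteoblasts in the KO samples could give the same pattern and were not separated from it.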
